A study of Arabidopsis thaliana with 12 samples.

How the data were processed

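Total RNA of seedling shoots was sequenced in 12 libraries, 3 for each combination of genotype (Col-0, cdk8-1) and sulfur supply (1.5 mM or 0 mM magnesium sulfate). Per the labels, seedlings were 10 days old, RNA was extracted with a NucleoSpin RNA Plant kit and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand. All 12 libraries carry one batch label, so no batch could be compared with the groups. The labels do not state whether replicates came from separate cultures, so p-values measure the spread between these samples. The numbers of the replicates are not stated to pair samples, and a block by number was run as an alternative only.

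The authors deposited 1 table of transcripts per 1000000 (TPM) for 32833 loci, 1 column per library. STAR 2.7.11b, featureCounts 2.0.8 and DESeq2 1.46 are named in the submitters' processing notes, with no role or order. The genome build and annotation are not given in the sources used here, so no coordinates are printed. Of the 12 columns, 11 sum to 1000000 and that of Col-0 with sulfate replicate 3 to 1004125.4, for a reason that the values do not show. Each value was found to be a whole number of reads divided by a gene length and scaled. With exonic lengths from a reference annotation for 25759 genes and a searched length for 149, whole reads were recovered to within 0.01 read for 100% of the values above 0, and 6925 loci were 0 throughout. The recovered reads gave the depth of each library, 17508583 to 25274363 reads in genes. They cover counting in genes only, and PCR duplicates cannot be told from separate molecules.

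Some losses lie in the table itself. All 133 chloroplast and 152 mitochondrial loci are at 0 in every library. Of 325 nuclear protein-coding genes whose exons are fully covered by exons on the other strand, 322 (99.1%) are listed at 0, against 2661 of 19961 (13.3%) without any overlap, so reads in such overlaps appear to have been given to neither gene. Levels of partly overlapped genes are then too low, and MYC2, GSTF11, CYP81F1 and LHCB1.5 could not be studied. Of 158 genes picked for naming, 15 have at least 10% of their exons in such overlaps. Near-identical gene copies, such as those of LHCB, RBCS and AOC, share reads that a gene table cannot place.

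Loci were given symbols from a reference table (99.1% of loci matched). Genes with a mean of at least 1 TPM over the 12 libraries were tested (19127) on log2(TPM + 1) with limma 3.58.1 in R 4.3.3. The model had a mean for each of the 4 groups, trended empirical Bayes moderation, 8 residual degrees of freedom and a median of 4.17 prior degrees of freedom. The 5 contrasts were without against with sulfate in Col-0 and in cdk8-1, cdk8-1 against Col-0 with and without sulfate, and the interaction, the response in cdk8-1 minus that in Col-0. Tests were two-sided, and p was adjusted within a contrast by Benjamini and Hochberg, with a threshold of 0.05 and no minimum fold change. Because the gene values of a library compete for one total, results were also computed after median-of-ratios scaling, and sulfur responses are given relative to the median gene.

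Before the data were examined, 23 gene lists with 346 genes were fixed (345 are in the table). They cover aliphatic and indolic glucosinolate synthesis, glucosinolate regulators, glucosinolate breakdown and transport, sulfur limitation markers, sulfate assimilation with cysteine and glutathione synthesis, jasmonate synthesis, jasmonate repressors and catabolism, the MYC and ERF branches of the jasmonate response, salicylate, camalexin, tryptophan, flavonoids, the Mediator complex, photosynthesis, senescence, abscisic acid, phosphate starvation, cell division, root markers, seed storage markers and reference genes. Some genes stand in 2 lists, such as BGLU28 and LOX2. Each list was tested against all other genes with camera of limma, with a preset correlation of 0.01 between genes and p adjusted over the 23 lists of a contrast. The test was repeated with an estimated correlation, and with fry, which asks if the genes of a list move one way on balance without comparing them with other genes. Of 39 calls with the preset correlation, 1 held with an estimated one. Lists of iron deficiency genes, ferritins and DNA damage genes were added after the data had been seen.

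Genes were named by a rule fixed before the data were examined. It takes CDK8, the 10 largest rises and 10 largest falls of each comparison of 2 groups among genes that passed with no overlap between the groups (5 and 5 in the interaction), up to 4 passing members of each list with the smallest p (up to 2 where none passed), and all regulators, sulfur limitation markers and jasmonate repressors. With 3 against 3 libraries, 10% of genes show no overlap by chance. The genes named in the text are a subset of these, picked after the values were seen. Only whether to name them was chosen then, and counts cover all genes.

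Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a minimum of 5 TPM, median-of-ratios and quantile scaling, moderation without trend and robust moderation, array weights, a replicate block, only the 6 libraries compared, a 2-fold minimum and leaving out each library in turn. Limma voom on recovered reads, and an estimated list correlation after median-of-ratios scaling, were added after the data had been seen. The tests were tried on simulated data with 18046 genes and 12 libraries, in which 200 genes changed in cdk8-1 without sulfate alone. The interaction test called 53.7% of those changed 1.5-fold, 86.6% at 2-fold and 100% at 4-fold, with 5 other genes called, and contrasts with no change gave 2 and 1 calls. A raised list of 37 genes was called and 0 of 22 random lists were. The simulated genes varied independently around the means of Col-0 with sulfate, with 1 shared dispersion of 0.00281 and no general sulfur response. Genes of the real lists were correlated (estimates of 0.0436 to 0.918), so these rates need not hold for the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.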

Results

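RNA from the shoots of 12 plate-grown Arabidopsis thaliana seedling samples was sequenced. The samples came from Col-0, the laboratory wild type, and from cdk8-1, a line mutated in CDK8, the gene of the kinase that belongs to the Mediator complex of transcription. Both lines had grown for 10 days on plates with 1.5 mM magnesium sulfate or on plates where magnesium chloride took its place, so that sulfate was 0 mM in the added magnesium salt and chloride was higher. Each of the 4 groups held 3 libraries, and values below are means ± SD of n = 3 in transcripts per 1000000 (TPM). The libraries of Col-0 with sulfate held 19491720 to 20470390 reads in genes, those of Col-0 without sulfate 19547338 to 25274363, those of cdk8-1 with sulfate 17508583 to 20370823 and those of cdk8-1 without sulfate 18434193 to 22594173. At these depths 1 read in a gene of 1 kilobase stood for 0.0710 to 0.0962 TPM. The title of the study names CDK8, jasmonate signaling, sulfur availability and chemical defense, and the design allows 5 comparisons: sulfur deprivation in each genotype, genotype at each sulfur supply, and their interaction. Of 32833 loci, 19127 had a mean of at least 1 TPM and were tested.

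Sulfur supply separated the libraries more than genotype did. The first principal component held 87.5% of the variance and parted the libraries with sulfate from those without. The second held 6.08% and parted the genotypes at each supply, with the wider gap without sulfate. Replicate libraries of a group correlated at r = 0.983 to 0.993 across genes, and libraries of Col-0 with and without sulfate at 0.649 to 0.672. The genes of the fixed list of nuclear photosynthesis genes, a part of all such genes, took 18.03% to 18.7% of all TPM in Col-0 with sulfate. Without sulfate they took 1.06% to 1.09%. In cdk8-1 they took 16.3% to 17.04% with sulfate and 2.76% to 3.45% without it. The values of a library share one total, so a loss in abundant genes can raise the values of others. The median tested gene had a log2 fold change of 0.46 under sulfur deprivation in Col-0 and 0.45 in cdk8-1, against 0.05 and 0.03 after median-of-ratios scaling. Changes under sulfur deprivation are therefore given relative to the median gene, while TPM levels are as deposited and tests are on the deposited scale. In the genotype comparisons the median gene had a log2 fold change of 0.07 with sulfate and 0.08 without it. All log2 values are of TPM + 1, which narrows the changes of genes near 0 TPM.

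CDK8 (AT5G63610), the gene that defines the mutant, was lower in every cdk8-1 library than in any Col-0 library. With sulfate it was at 22.8 ± 1.71 TPM in Col-0 and 3.99 ± 1.02 TPM in cdk8-1, a log2 fold change of -2.27 ± 0.13 (SE, adjusted p = 1.53e-06). Without sulfate the levels were 33.2 ± 0.451 and 5.49 ± 0.514 TPM, a log2 fold change of -2.40 (adjusted p = 5.73e-08). Transcripts of the locus thus remained in the mutant at 2.96 to 6.09 TPM. The interaction of CDK8 was -0.13 (adjusted p = 0.65), a value of 0.02 without cdk8-1 with sulfate replicate 3. On the deposited scale CDK8 was higher without sulfate in Col-0, by 0.52 (adjusted p = 0.00224), and in cdk8-1, by 0.40 (adjusted p = 0.0132). Neither call held after median-of-ratios scaling, where the values were 0.08 and 0.02, after quantile scaling or in limma voom on recovered reads. In cdk8-1 the call also ended without cdk8-1 with sulfate replicate 1 (0.24) and without cdk8-1 without sulfate replicate 3 (0.33). In the list of the Mediator complex and its CDK8 module, 2 of 17 members were higher and CDK8 alone was lower in cdk8-1 with sulfate (3 and 1 adjusted over the list alone; camera adjusted p = 0.832). The 2 higher members were MED12 (AT4G00450) (0.28) and MED14 (AT3G04740) (0.32), and both lost the call after median-of-ratios scaling. The call of MED12 also ended without Col-0 with sulfate replicate 1 (0.24), cdk8-1 with sulfate replicate 1 (0.27) or its replicate 3 (0.24). That of MED14 ended without Col-0 with sulfate replicate 1 (0.22) or replicate 1 (0.34), 2 (0.29) or 3 (0.33) of cdk8-1 with sulfate.

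**Figure D1:**
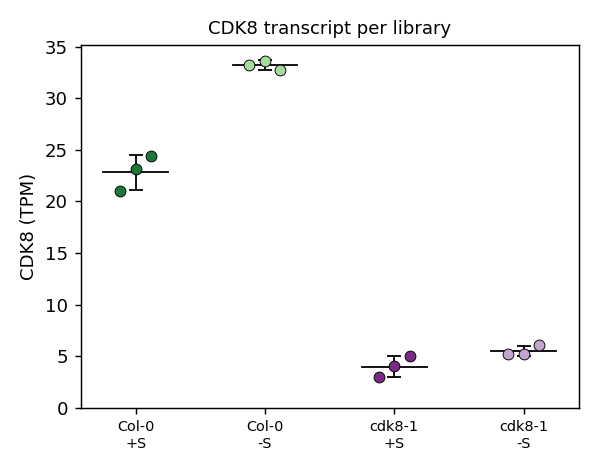
CDK8 level in TPM in each of the 12 libraries, grouped by genotype and sulfur supply. Points are libraries and bars show the group mean and SD. All cdk8-1 libraries sit between 2.96 and 6.09 TPM, and all Col-0 libraries between 21.0 and 33.6 TPM.

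In Col-0 without sulfate, the camera test called sulfur limitation marker, salicylate, camalexin, tryptophan and senescence lists higher and photosynthesis, cell division and aliphatic glucosinolate lists lower. None of these 8 calls held with an estimated correlation (adjusted p of 0.505 to 0.921). LSU1 (AT3G49580), a gene long known for its induction by sulfur deficiency, went from 16.0 ± 17.1 to 1241 ± 81.4 TPM, a log2 change of 6.20 relative to the median gene (adjusted p = 4.84e-07). BGLU30 (AT3G60140), a beta-glucosidase that acts on glucosinolates, went from 0.189 ± 0.0209 to 3229 ± 189 TPM (10.95, adjusted p = 7.02e-17). TGG2 (AT5G25980), a classical myrosinase, went the other way, from 607 ± 49.1 to 0.0516 ± 0.0542 TPM (-9.63, adjusted p = 3.25e-14). CA1 (AT3G01500), a chloroplast carbonic anhydrase, fell from 1394 ± 17.97 to 2.98 ± 0.787 TPM (-8.93, adjusted p = 2.44e-13).

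Of the 19127 genes, 16248 (84.9%) passed the limma test at an adjusted p below 0.05, 10736 of them higher and 5512 lower without sulfate. With median-of-ratios scaling 15498 passed, 8011 higher and 7487 lower, and 275 genes that passed on both scales did so with opposite signs. Counts at a change of at least 2-fold were 5789 higher and 3314 lower. List counts are from the deposited scale. For sulfur deprivation each is followed by that after median-of-ratios scaling where they differ, and for genotype the differing ones are given together. Adjusted over the list alone the counts were the same, except for sulfate assimilation with 9 higher and 3 lower and flavonoid synthesis with 15 and 4.

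Of the 19 sulfur limitation markers, 18 rose and 1 fell (17 and 1 after scaling), with a median of 3.13 relative to the median gene (camera adjusted p = 0.00364, and adjusted p = 0.887 with an estimated correlation). Sulfate transporter genes were among them: SULTR1;2 (AT1G78000) rose from 13.5 ± 1.76 to 288 ± 7.73 TPM, a relative change of 3.86, and SULTR1;1 (AT4G08620) from 0.0233 ± 0.0404 to 24.7 ± 5.72 TPM. SDI1 (AT5G48850), which encodes a repressor of glucosinolate synthesis, went from 22.6 ± 23.1 to 1379.9 ± 104 TPM (5.87), with a wide spread between the libraries with sulfate. APR1 (AT4G04610) and APR3 (AT4G21990), genes of the sulfate-reducing enzyme APS reductase, rose by 2.38 and 2.01. The vascular transporter gene SULTR2;1 (AT5G10180) was the member that fell (-1.23). In the wider list of sulfate assimilation, cysteine and glutathione synthesis, 10 of 20 members were higher and 3 lower, and after scaling 5 were higher and 11 lower (camera adjusted p = 0.858). SERAT3;2 (AT4G35640), a serine acetyltransferase gene, was higher by 2.36 and ATPS4 (AT5G43780), an ATP sulfurylase gene, changed by -3.15 on the log2 scale.

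Aliphatic glucosinolate synthesis genes fell as a list, with 16 of 25 members lower and 8 higher (17 and 4 after scaling) and a relative median of -2.03 (camera adjusted p = 0.00364, and adjusted p = 0.921 with an estimated correlation). MAM1 (AT5G23010), which opens the chain elongation of methionine, fell from 284 ± 26.0 to 19.2 ± 4.66 TPM (-4.30), and GSTU20 (AT1G78370) from 474 ± 67.2 to 45.7 ± 5.87 TPM (-3.80). Their regulators MYB28 (AT5G61420) and MYB29 (AT5G07690) changed by -1.10 and -3.94 relative to the median gene. Among indolic glucosinolate genes 8 of 11 were higher and 3 lower (6 and 3 after scaling, camera adjusted p = 0.858). SOT16 (AT1G74100), a sulfotransferase gene, rose by 0.85, while CYP79B3 (AT2G22330), for the first step from tryptophan, changed by -2.35 on the log2 scale. The indolic regulators also differed in sign, as MYB51 (AT1G18570) (0.88) and MYB122 (AT1G74080) (2.64) rose and MYB34 (AT5G60890) fell (-2.13). In all, 3 of 7 regulators were higher and 3 lower (3 and 4 after scaling, camera adjusted p = 0.717). In glucosinolate breakdown and transport 9 of 16 were higher and 7 lower (8 and 7 after scaling, camera adjusted p = 0.858). Next to BGLU30, BGLU28 (AT2G44460) rose from 1.61 ± 0.165 to 2479.7 ± 194 TPM and the nitrile-specifier gene NSP5 (AT5G48180) from 114 ± 4.59 to 2857 ± 222 TPM.

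All 20 salicylate genes were higher, with a relative median of 3.15 (camera adjusted p = 6.81e-05, and adjusted p = 0.552 with an estimated correlation), among them the pathogenesis-related gene PR1 (AT2G14610), from 3.45 ± 2.12 to 1443 ± 226 TPM, and PBS3 (AT5G13320), for salicylate synthesis, by 6.27. All 7 genes of synthesis of camalexin, the indolic phytoalexin, were higher, with a relative median of 3.99 (camera adjusted p = 0.0255, and adjusted p = 0.765 with an estimated correlation). Of these CYP71A12 (AT2G30750) changed by 6.31 and PAD3 (AT3G26830), for the last step, by 6.14. The 7 genes of tryptophan synthesis, which feeds camalexin and indolic glucosinolates, were all higher, with a relative median of 1.38 (camera adjusted p = 0.0255, and adjusted p = 0.887 with an estimated correlation), and IGPS (AT2G04400) changed by 1.77. Leaf senescence genes were higher in 11 of 13 and lower in 1, with a relative median of 1.71 (camera adjusted p = 0.0203, and adjusted p = 0.505 with an estimated correlation), led by SAG13 (AT2G29350) (6.84) and SRG1 (AT1G17020) (5.86).

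Every one of the 22 nuclear photosynthesis genes tested fell, with a relative median of -4.63 (camera adjusted p = 2.14e-16, and adjusted p = 0.505 with an estimated correlation). RBCS3B (AT5G38410), for the small subunit of Rubisco, fell from 9995 ± 274 to 148 ± 5.53 TPM and RBCS1A (AT1G67090) from 15879 ± 269 to 855 ± 13.4 TPM. All 16 cell division genes fell as well, with a relative median of -2.60 (camera adjusted p = 1.04e-07, and adjusted p = 0.505 with an estimated correlation), as in the mitotic cyclin gene CYCB1;2 (AT5G06150) (-4.67) and CDC20.1 (AT4G33270) (-4.53).

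Jasmonate lists did not pass as lists in Col-0. Jasmonate biosynthesis had 9 of 15 members higher and 1 lower, and 6 and 5 after scaling (camera adjusted p = 0.347), with the lipoxygenase gene LOX2 (AT3G45140) higher by 2.58. Jasmonate repressors and catabolism had 10 of 17 higher and 3 lower (10 and 4 after scaling, camera adjusted p = 0.574). JAZ1 (AT1G19180) rose by 3.37 and JOX3 (AT3G55970), for jasmonate hydroxylation, by 4.196, while JAZ9 (AT1G70700) changed by -3.07. In the MYC branch of the jasmonate response 6 of 10 were higher and 3 lower (camera adjusted p = 0.858), and in the ERF branch 3 of 4 were higher and 1 lower (adjusted p = 0.574).

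The other lists did not pass either. Flavonoid and anthocyanin synthesis had 14 of 19 higher and 4 lower (13 and 4 after scaling, adjusted p = 0.301), including the activator gene PAP1 (AT1G56650) (4.199) and DFR (AT5G42800) (3.74). Abscisic acid response had 4 higher and 9 lower of 14 (4 and 10 after scaling, adjusted p = 0.206), phosphate starvation 4 and 6 of 13 (0.301), and Mediator 15 and 1 of 17 (6 and 3 after scaling, 0.209). Root markers had 1 of 3 higher (adjusted p = 0.885) and seed storage markers none of 6 past the test (0.55). Of the common reference genes 6 of 9 were higher and 2 lower (4 and 4 after scaling, adjusted p = 0.654), with UBQ10 (AT4G05320) at 1196 ± 64.0 TPM with sulfate and 4888 ± 187 TPM without. The test direction was downward against a positive median and mean for glucosinolate breakdown, sulfate assimilation and root markers, and the mean of the phosphate list was positive against a negative median and test.

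In cdk8-1 without sulfate, 5 of the 8 lists called in Col-0 were called in the same direction and jasmonate biosynthesis was called higher. None of these 6 calls held with an estimated correlation (adjusted p of 0.57 to 0.774). LSU1 went from 11.3 ± 11.5 to 1324 ± 164 TPM, a log2 change of 6.71 relative to the median gene, and SDI1 from 9.84 ± 9.23 to 1595 ± 145 TPM (7.08). BGLU30 went from 0.329 ± 0.152 to 2270.1 ± 43.1 TPM and BGLU28 from 0.571 ± 0.408 to 1567 ± 109.6 TPM. TGG2 fell from 303 ± 19.2 to 0.552 ± 0.290 TPM, and CA1 from 1257 ± 40.7 to 24.3 ± 6.28 TPM (-6.11, adjusted p = 1.19e-11).

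Here 15607 genes (81.6%) passed, 10877 higher and 4730 lower without sulfate, and 5012 and 2395 of them by at least 2-fold. With median-of-ratios scaling 14502 passed, 7404 higher and 7098 lower, and 308 genes that passed on both scales had opposite signs. Adjusted over the list alone the list counts were the same, except for abscisic acid response with 4 higher and 2 lower and seed storage markers with 0 lower.

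Of the 19 sulfur limitation markers 18 rose and 1 fell (17 and 1 after scaling), with a relative median of 3.01 (camera adjusted p = 0.00126, and adjusted p = 0.774 with an estimated correlation). SULTR1;2 changed by 3.62 and GGCT2;1 (AT5G26220), for glutathione breakdown, by 6.91. Aliphatic glucosinolate genes fell in 17 of 25 and rose in 3 (19 and 3 after scaling), with a relative median of -1.45 (camera adjusted p = 0.00016, and adjusted p = 0.774 with an estimated correlation). MAM1 changed by -5.06, from 215 ± 20.08 to 7.83 ± 0.522 TPM, and GSTU20 by -3.53 relative to the median gene. Indolic genes had 6 of 11 higher and 3 lower (4 and 3 after scaling, camera adjusted p = 0.642). Regulators had 3 of 7 higher and 3 lower (3 and 4 after scaling, adjusted p = 0.501), with MYB51 at 0.78, MYB28 at -1.10 and MYB29 at -3.32. Breakdown and transport had 9 of 16 higher and 7 lower (adjusted p = 0.952), and sulfate assimilation 9 and 5 of 20 (4 and 11 after scaling, 0.505).

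Jasmonate biosynthesis genes rose as a list in cdk8-1, with all 15 of 15 higher (10 after scaling) and a relative median of 0.89 (camera adjusted p = 0.0263, and adjusted p = 0.57 with an estimated correlation). The list also lost its call with a minimum of 5 TPM. LOX2 rose by 2.47, and AOC2 (AT3G25770), an allene oxide cyclase gene with near-identical copies, by 2.14. Repressors and catabolism had 10 of 17 higher and 2 lower (9 and 2 after scaling, adjusted p = 0.642), the MYC branch 8 and 2 of 10 (0.423) and the ERF branch 3 and 0 of 4 (0.376). JAZ1 changed by 3.13, JAZ9 by -2.08, and VSP2 (AT5G24770), a vegetative storage protein gene and classical jasmonate marker, went from 14.6 ± 4.64 to 93.8 ± 37.8 TPM (2.104).

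Salicylate genes rose in 19 of 20, with a relative median of 2.67 (camera adjusted p = 0.000203, and adjusted p = 0.57 with an estimated correlation), and PBS3 changed by 4.79. Camalexin genes were higher in 6 of 7 (adjusted p = 0.115) and tryptophan genes in 6 of 7 (0.376), or 2 higher and 1 lower after scaling. The camalexin and senescence lists passed after median-of-ratios scaling, with adjusted p = 0.0150 and adjusted p = 0.00909 (both adjusted p = 0.469 on that scale with an estimated correlation). PAD3 rose from 0.985 ± 0.632 to 52.8 ± 15.6 TPM and IGPS by 0.86. Photosynthesis genes fell in 22 of 22, with a relative median of -2.90 (camera adjusted p = 3.14e-17, and adjusted p = 0.57 with an estimated correlation), and RBCS3B fell from 9569.8 ± 56.1 to 554 ± 76.8 TPM. Cell division genes fell in 12 of 16 and rose in 1 (14 and 1 after scaling), with a relative median of -2.18 (camera adjusted p = 1.52e-05, and adjusted p = 0.57 with an estimated correlation). Senescence genes were higher in 10 of 13 and lower in 1 (10 and 2 after scaling, adjusted p = 0.0858), with SAG13 at 5.00.

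Among the remaining lists of this comparison, flavonoid synthesis had 13 of 19 higher and 4 lower (12 and 4 after scaling, adjusted p = 0.505), with DFR at 4.18. Counts higher and lower were 13 and 1 of 17 for Mediator (5 and 3 after scaling), 4 and 3 of 14 for abscisic acid response (3 and 4), and 5 and 5 of 13 for phosphate starvation (4 and 6). They were 1 and 0 of 3 for root markers, 0 and 1 of 6 for seed storage markers and 7 and 2 of 9 for reference genes (2 and 3 after scaling). Their camera adjusted p values were 0.364, 0.505, 0.37, 0.797, 0.168 and 0.642. The test direction was downward against a positive median and mean for indolic genes, glucosinolate breakdown and sulfate assimilation, and against a positive mean for abscisic acid response and phosphate starvation. The seed storage transcripts summed to 232 TPM in cdk8-1 with sulfate replicate 1, and to at most 6.30 TPM in any other library.

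The response to sulfur deprivation had the same direction in both genotypes for most genes and was smaller in cdk8-1. Across the 19127 genes the log2 changes in Col-0 and cdk8-1 correlated at r = 0.932 (Spearman rho = 0.930), and genes are not independent replicates. The slope of the change in cdk8-1 on that in Col-0, corrected for noise, was 0.74, and the SD of the changes in cdk8-1 was 0.784 of that in Col-0. In both genotypes 9934 genes rose and 4405 fell, where independent lists would share 6105.3 and 1363.1, and 178 genes passed with opposite signs. Of the genes called in either genotype, 72.0% had the smaller change in cdk8-1.

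The difference between the responses passed the interaction test in 5171 genes (27.0%), 2831 with a positive and 2340 with a negative value. Of these, 2157 had risen in Col-0 with a smaller or no rise in cdk8-1, and 2117 had fallen in Col-0 with a smaller or no fall in cdk8-1. A larger rise in cdk8-1 was found for 341 genes and a larger fall for 70. Genes that rose in Col-0 and fell in cdk8-1 numbered 47, those with the opposite pair of signs 131, those called in cdk8-1 alone 238 (higher) and 63 (lower), and 7 were called in neither. After median-of-ratios scaling 5153 genes passed. By at least 2-fold the counts were 1024 positive and 744 negative.

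**Figure D2:**
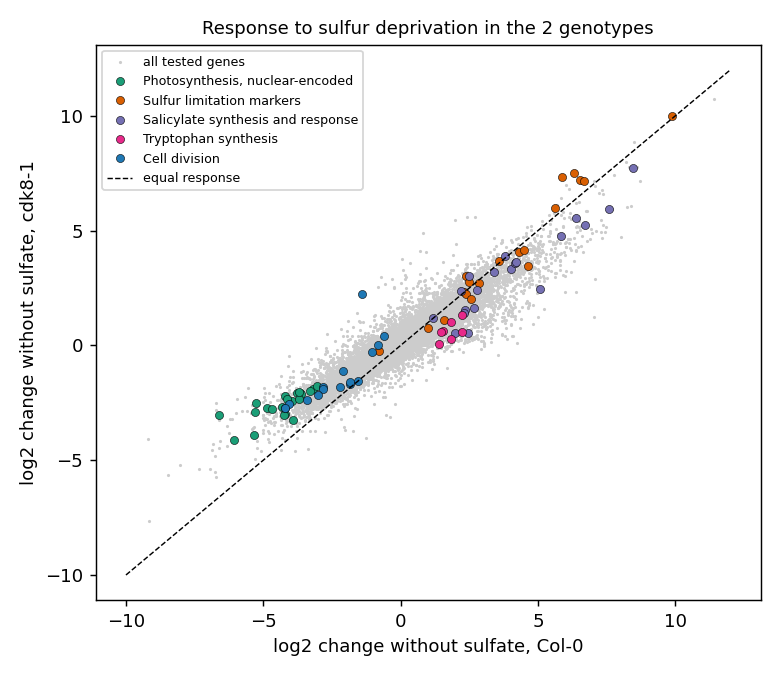
Log2 fold change of TPM + 1 without against with sulfate for each tested gene, Col-0 on the horizontal and cdk8-1 on the vertical axis, on the deposited scale with no shift to the median gene. The cloud follows a line flatter than the diagonal, with a noise-corrected slope of 0.74.

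Photosynthesis genes had the smallest camera adjusted p of the interaction with the preset correlation (adjusted p = 1.39e-24). All 22 of 22 members were positive, with a median interaction of 1.60, and thus a smaller fall in cdk8-1. With an estimated correlation the camera adjusted p was 0.193, and that of senescence 0.192. LHCB2.2 (AT2G05070), for a light-harvesting protein, kept 145 ± 13.9 TPM without sulfate in Col-0 and 1013 ± 231 TPM in cdk8-1, an interaction of 2.78 ± 0.18 (SE). That of RBCS3B was 1.95, and both gene families hold near-identical copies between which reads are hard to place. Cell division genes were positive in 10 of 16 (12 adjusted over the list alone), with a median of 0.96 (camera adjusted p = 3.22e-06, and adjusted p = 0.45 with an estimated correlation). The mitotic cyclin gene CYCB1;1 (AT4G37490) had the value of 3.62 (adjusted p = 5.87e-07), with levels of 7.30 ± 1.35 TPM with and 2.14 ± 0.443 TPM without sulfate in Col-0, and of 7.70 ± 0.961 and 39.5 ± 4.47 TPM in cdk8-1. CYCB1;2 and CDC20.1 had interactions of 1.47 and 1.49.

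Tryptophan, camalexin, salicylate and senescence lists had negative interaction calls, none of which held with an estimated correlation (adjusted p of 0.192 to 0.513). Responses over all genes were smaller in cdk8-1 (slope 0.74). Lists that rose in Col-0 can therefore have negative values, and lists that fell positive ones, without an effect of their own. Whether any list went beyond that was not tested. All 7 tryptophan synthesis genes had a negative interaction, with a median of -0.91 (camera adjusted p = 1.24e-06, and adjusted p = 0.327 with an estimated correlation). TSA1 (AT3G54640), for tryptophan synthase alpha, reached 185 ± 14.7 TPM without sulfate in Col-0 and 66.7 ± 9.13 TPM in cdk8-1, from 51.4 ± 7.58 and 54.0 ± 3.70 TPM (interaction -1.54, adjusted p = 2.53e-05). Camalexin synthesis was negative in 5 of 7, with a median of -1.88 (camera adjusted p = 0.000516, and adjusted p = 0.327 with an estimated correlation), including CYP71A12 (-2.21) and FOX1 (AT1G26380) (-2.16). PAD3 had an interaction of -1.83, which lost its call in limma voom on recovered reads. Salicylate genes were negative in 8 of 20 (1 positive and 10 negative adjusted over the list alone), with a median of -0.77 (camera adjusted p = 0.000391, and adjusted p = 0.513 with an estimated correlation), including PBS3 (-1.49). Senescence genes were negative in 7 of 13 (9 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 9.51e-05, and adjusted p = 0.192 with an estimated correlation), including SRG1 (-1.63) and the sugar exporter gene SWEET15 (AT5G13170) (-3.94). GSH1 (AT4G23100), for the first step of glutathione synthesis, had an interaction of -1.09.

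Jasmonate genes went both ways in the interaction. VSP2 was at 62.5 ± 16.9 TPM with and 33.6 ± 3.01 TPM without sulfate in Col-0, and at 14.6 ± 4.64 and 93.8 ± 37.8 TPM in cdk8-1, an interaction of 3.39 ± 0.43 (SE, adjusted p = 0.000123). VSP1 (AT5G24780) (1.69), BGLU18 (AT1G52400) (2.77) and OPR3 (AT2G06050) (0.86), for jasmonate synthesis, were positive too, while JOX3 was negative (-3.03). By list, 5 of 15 biosynthesis genes were positive and 1 negative (6 and 1 adjusted over the list alone). The counts were 1 and 3 of 17 for repressors and catabolism, 4 and 2 of 10 for the MYC branch and 1 and 1 of 4 for the ERF branch (1 and 0 after scaling). Their camera adjusted p values were 0.249, 0.465, 0.535 and 0.998.

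Sulfur limitation markers did not pass the interaction test as a list, with 3 positive and 3 negative of 19 and a median of 0.08 (camera adjusted p = 0.847). SULTR4;2 (AT3G12520) (0.65) and SULTR2;1 (0.55) were positive and SULTR4;1 (AT5G13550) (-0.53) negative. Aliphatic glucosinolate genes had 2 positive and 4 negative of 25 (1 and 4 adjusted over the list alone), and indolic genes 2 and 2 of 11, with CYP79B2 (AT4G39950) at -2.30. Breakdown and transport had 4 and 4 of 16 (5 and 5 adjusted over the list alone), regulators 0 and 2 of 7, and sulfate assimilation 1 and 3 of 20. Positive and negative counts were 1 and 4 of 19 for flavonoid synthesis, 5 and 1 of 14 for abscisic acid response, 1 and 1 of 13 for phosphate starvation, 0 and 1 of 17 for Mediator (0 adjusted over the list alone) and 0 and 1 of 9 for reference genes. No root marker of 3 and no seed storage marker of 6 passed. None of these lists passed the camera test, with adjusted p from 0.243 to 0.847. Among the largest interactions of single genes, ABCG40 (AT1G15520), for a transporter, was at -5.79, TH8 (AT1G69880), for a thioredoxin, at -4.18 and AT2G10940 at 3.89. Median and test differed in sign for sulfur markers, sulfate assimilation and the ERF branch.

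With sulfate present, the camera test called 10 lists, all lower in cdk8-1 and jasmonate, abscisic acid and indolic glucosinolate lists among them. None of these calls held with an estimated correlation (adjusted p of 0.103 to 0.666). VSP2 was at 62.5 ± 16.9 TPM in Col-0 and 14.6 ± 4.64 TPM in cdk8-1, a log2 fold change of -2.03 ± 0.31 (SE, adjusted p = 0.00133). MYB51, a regulator of indolic glucosinolates, fell from 22.5 ± 6.57 to 8.18 ± 1.66 TPM (-1.33, adjusted p = 0.00103). bHLH39 (AT3G56980), a transcription factor induced by iron deficiency, rose from 0.462 ± 0.426 to 13.3 ± 5.75 TPM (3.25, adjusted p = 5.62e-05), and its relatives bHLH38 (AT3G56970) (3.21) and BHLH100 (AT2G41240) (3.03) rose alike. Exons of bHLH38 overlap those of another gene on the other strand over 35.7% of their length, where reads appear to have been left uncounted.

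In all 2618 genes (13.7%) passed, 1693 higher and 925 lower in cdk8-1, and 92 and 193 by at least 2-fold. With median-of-ratios scaling 2074 passed, 850 higher and 1224 lower. List counts higher and lower then became 1 and 6 for aliphatic genes, 0 and 6 for indolic genes, 1 and 1 for regulators, 2 and 4 for breakdown and transport, 1 and 4 for sulfate assimilation and 0 and 6 for jasmonate repressors and catabolism. They became 1 and 0 for salicylate, 0 and 1 for camalexin, 0 and 1 for flavonoid synthesis, 0 and 1 for Mediator, 1 and 9 for photosynthesis, 0 and 7 for abscisic acid response and 1 and 0 for reference genes. The count of genes was 1940 (1103 higher and 837 lower) without cdk8-1 with sulfate replicate 1, the library with the seed storage transcripts (232 TPM). It was 1751 (1130 and 621) without replicate 2 and 1744 (1090 and 654) without replicate 3 of that group. With the spread estimated from only these 6 libraries 1183 genes passed (661 and 522).

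Jasmonate lists were lower. Biosynthesis genes were lower in 8 of 15 (8 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 3.66e-06, and adjusted p = 0.152 with an estimated correlation). LOX3 (AT1G17420) changed by -1.25 (adjusted p = 0.00145) and OPR3 by -0.70 (adjusted p = 0.00142). Repressors and catabolism were lower in 5 of 17 (9 adjusted over the list alone), with a median of -0.57 (camera adjusted p = 1.36e-07, and adjusted p = 0.202 with an estimated correlation). JAZ6 (AT1G72450) (-0.81), JAZ9 (-0.80), CYP94C1 (AT2G27690) (-1.53) and JOX2 (AT5G05600) (-0.95) were among them, and all lost the call with the spread of only the 6 libraries. JAZ1 stood at -1.31 (adjusted p = 0.0572) and passed without Col-0 with sulfate replicate 3 (-1.70) or cdk8-1 with sulfate replicate 1 (-1.76), and with array weights. In the MYC branch 6 of 10 were lower, with a median of -0.74 (camera adjusted p = 1.63e-05, and adjusted p = 0.103 with an estimated correlation), including CORI3 (AT4G23600) (-1.58), and LOX2 stands in this list and in that of biosynthesis. The ERF branch had 1 of 4 lower (adjusted p = 0.118).

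Abscisic acid response genes were lower in 6 of 14 (8 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 1.36e-07, and adjusted p = 0.177 with an estimated correlation), including RAB18 (AT5G66400), a dehydrin gene (-1.63, adjusted p = 0.000933). Indolic glucosinolate genes were lower in 5 of 11 (8 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 1.36e-07, and adjusted p = 0.154 with an estimated correlation). CYP81F2 (AT5G57220), for modification of indolic glucosinolates, changed by -1.71 (adjusted p = 0.000914) and CYP83B1 (AT4G31500) by -0.94. Aliphatic genes were lower in 5 and higher in 1 of 25 (6 and 3 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.00876, and adjusted p = 0.666 with an estimated correlation), and the higher one was MAM3 (AT5G23020) (0.95). In breakdown and transport 4 of 16 were lower and 3 higher (4 and 4 adjusted over the list alone, camera adjusted p = 0.358). ESM1 (AT3G14210), which favors isothiocyanate formation, changed by -2.100 and TGG2 by -0.998, while NSP1 (AT3G16400) (0.98) and TGG1 (AT5G26000) (0.53) rose. Regulators had 2 higher and 1 lower of 7 (3 and 1 adjusted over the list alone, adjusted p = 0.935).

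Sulfur limitation markers were lower in 3 of 19, with a median of -0.20 (camera adjusted p = 0.0114, and adjusted p = 0.605 with an estimated correlation), and SULTR2;1 changed by -0.52. Sulfate assimilation had 3 lower and 2 higher of 20 (4 and 2 adjusted over the list alone), with a median of -0.03 (camera adjusted p = 0.0437, and adjusted p = 0.502 with an estimated correlation). That list lost its call with no filter, with a minimum of 5 TPM and with a replicate block. Tryptophan synthesis was lower in 2 of 7, with a median of -0.17 (camera adjusted p = 0.016, and adjusted p = 0.537 with an estimated correlation). Photosynthesis genes were lower in 8 and higher in 1 of 22 (9 and 2 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 3.81e-06, and adjusted p = 0.502 with an estimated correlation). With quantile normalization 1 was lower and 1 higher and the list lost its call, while PSAF (AT1G31330), of photosystem I, stood at -0.69 in the main test (adjusted p = 0.000139).

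Other lists did not pass with sulfate in the main test. Higher and lower counts were 2 and 0 of 20 for salicylate, 1 and 0 of 7 for camalexin (1 and 2 adjusted over the list alone), 1 and 1 of 19 for flavonoid synthesis (0 and 1) and 0 and 3 of 13 for senescence (2 and 3). They were 1 and 0 of 16 for cell division and 2 and 0 of 9 for reference genes (3 and 0 adjusted over the list alone). No gene passed in phosphate starvation, root markers or seed storage markers, whose median of 1.66 came with the transcripts of cdk8-1 with sulfate replicate 1 and gave a camera adjusted p = 0.105, or 0.0248 after median-of-ratios scaling (adjusted p = 0.564 on that scale with an estimated correlation). Median, mean and test differed in sign for regulators, breakdown, salicylate, camalexin, Mediator and cell division. Among single genes, LTP3 (AT5G59320), for a lipid transfer protein, went from 19.4 ± 12.3 to 0.898 ± 0.859 TPM (-3.36), AT3G57880 changed by -2.59 and AT1G13609 by 4.13. AT3G22235 was listed at 0 in all Col-0 libraries with sulfate and at 34.0 ± 23.5 TPM in cdk8-1. Without sulfate AT3G22235 was at 0 to 0.103 TPM in the Col-0 libraries and at 383 to 459 TPM in those of cdk8-1 (8.63).

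Without sulfate, the camera test called 9 lists, with photosynthesis and cell division higher in cdk8-1 than in Col-0. Tryptophan, camalexin, indolic glucosinolate, senescence, salicylate and flavonoid lists were lower, as were jasmonate repressors and catabolism. Of these only senescence kept its call with an estimated correlation (adjusted p = 0.0406, against 0.193 to 0.719). CYCB1;1 was at 2.14 ± 0.443 TPM in Col-0 and 39.5 ± 4.47 TPM in cdk8-1, a log2 fold change of 3.69 ± 0.14 (SE, adjusted p = 7.14e-09). CYP79B2, for the first step from tryptophan to indolic glucosinolates and camalexin, was at 146 ± 24.8 and 14.9 ± 3.51 TPM (-3.23, adjusted p = 3.2e-06). ABCG40 was at 332 ± 33.4 and 4.78 ± 1.62 TPM (-5.88, adjusted p = 5.93e-10). LHCB2.2 was higher in cdk8-1 by 2.78 and LHCB1.1 (AT1G29920) by 2.32, both from families with near-identical copies.

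Here 7900 genes (41.3%) passed, 5028 higher and 2872 lower in cdk8-1, and 1018 and 796 by at least 2-fold. With median-of-ratios scaling 7635 passed, 3996 higher and 3639 lower. List counts higher and lower then became 3 and 10 for aliphatic genes, 1 and 2 for regulators, 5 and 7 for breakdown and transport, 3 and 8 for sulfate assimilation, 0 and 12 for salicylate and 1 and 7 for flavonoid synthesis. They became 1 and 2 for Mediator, 1 and 4 for abscisic acid response, 1 and 3 for phosphate starvation, 13 and 0 for cell division and 2 and 2 for reference genes. The root markers summed to 86.1 TPM in cdk8-1 without sulfate replicate 1 and to 4.92 to 31.8 TPM in the other libraries, and 6955 genes passed without that library. The effects of genotype with and without sulfate correlated at r = 0.216 across genes (Spearman rho = 0.159). At both supplies 683 genes were higher and 368 lower in cdk8-1, where independent lists would share 445 and 138.9, and 391 passed with opposite signs. By at least 2-fold, 30 genes were higher and 65 lower at both supplies.

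All 22 photosynthesis genes were higher in cdk8-1 without sulfate, with a median of 1.39 (camera adjusted p = 6.74e-18, and adjusted p = 0.193 with an estimated correlation). Cell division genes were higher in 14 of 16 (15 adjusted over the list alone), with a median of 0.89 (camera adjusted p = 5.44e-06, and adjusted p = 0.308 with an estimated correlation), including CYCB1;2 (1.53) and CDC20.1 (1.39). Senescence genes were lower in 10 of 13, with a median of -0.90 (camera adjusted p = 9.66e-08, and adjusted p = 0.0406 with an estimated correlation), the one list call that held with the estimated correlation. WRKY6 (AT1G62300) changed by -1.64 and SGR1 (AT4G22920), for chlorophyll breakdown, by -0.90.

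All 7 tryptophan synthesis genes were lower, with a median of -1.40 (camera adjusted p = 2.06e-08, and adjusted p = 0.193 with an estimated correlation), as TSB1 (AT5G54810) (-1.52), TSA1 (-1.47) and ASA1 (AT5G05730) (-1.46). Camalexin genes were lower in 6 of 7, with a median of -1.73 (camera adjusted p = 1.92e-05, and adjusted p = 0.193 with an estimated correlation), including PAD3, at 237 ± 25.7 TPM in Col-0 and 52.8 ± 15.6 TPM in cdk8-1. Indolic glucosinolate genes were lower in 10 of 11 (10 lower and 1 higher adjusted over the list alone), with a median of -0.72 (camera adjusted p = 1.36e-05, and adjusted p = 0.206 with an estimated correlation). CYP81F2 changed by -2.21 and MYB51, the regulator of indolic glucosinolates named above, by -1.44. Aliphatic genes had 5 higher and 9 lower of 25 (6 and 9 adjusted over the list alone, camera adjusted p = 0.113), with GSL-OH (AT2G25450) at -1.74 and MAM1 at -1.17. Regulators had 3 higher and 2 lower of 7 (adjusted p = 0.422) and breakdown 5 and 6 of 16 (5 and 7 adjusted over the list alone, 0.319). NSP1 was higher by 2.12 and PYK10 (AT3G09260), a beta-glucosidase gene, by 1.3.

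Jasmonate repressors and catabolism were lower in 9 of 17 (10 adjusted over the list alone), with a median of -1.24 (camera adjusted p = 3.68e-05, and adjusted p = 0.308 with an estimated correlation), including JAZ1 (-1.57), JOX2 (-1.49) and JOX3 (-2.76). JOX4 (AT2G38240) was at 77.9 ± 30.5 TPM in Col-0 and 4.43 ± 1.24 TPM in cdk8-1 (-3.81). In the MYC branch 3 of 10 were higher and 4 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.303). VSP1 (1.93) and BGLU18 (2.67) were higher, and the transcription factor genes ANAC019 (AT1G52890) (-2.79) and ANAC055 (AT3G15500) (-2.49) lower. Biosynthesis had 4 higher and 5 lower of 15 (adjusted p = 0.422), with LOX4 (AT1G72520) at -2.19, and the ERF branch 1 of 4 lower (0.422). Salicylate genes were lower in 11 of 20 (11 lower and 1 higher adjusted over the list alone), with a median of -0.59 (camera adjusted p = 3.19e-05, and adjusted p = 0.308 with an estimated correlation), as GRXS13 (AT1G03850) (-1.07) and PBS3 (-1.37).

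Sulfur limitation markers had 1 higher and 5 lower of 19 (camera adjusted p = 0.0812), SULTR1;2 among the lower ones (-0.40). Sulfate assimilation had 4 higher and 7 lower of 20 (4 and 9 adjusted over the list alone, 0.0539), with GSH1 at -1.10 and SIR (AT5G04590), the sulfite reductase gene, at -0.91. Flavonoid synthesis was lower in 6 and higher in 2 of 19, with a median of -0.45 (camera adjusted p = 0.0163, and adjusted p = 0.719 with an estimated correlation). The flavonoid call ended after median-of-ratios scaling (adjusted p = 0.0545), and PAP1 changed by -1.90. Higher and lower counts were 2 and 4 of 14 for abscisic acid response, 2 and 3 of 13 for phosphate starvation, 2 and 1 of 17 for Mediator (1 and 1 adjusted over the list alone) and 2 and 1 of 9 for reference genes, and none for root and seed storage markers. None of these passed the camera test. Median, mean and test differed in sign for aliphatic genes, regulators, breakdown, jasmonate biosynthesis and phosphate starvation.

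**Figure D3:**
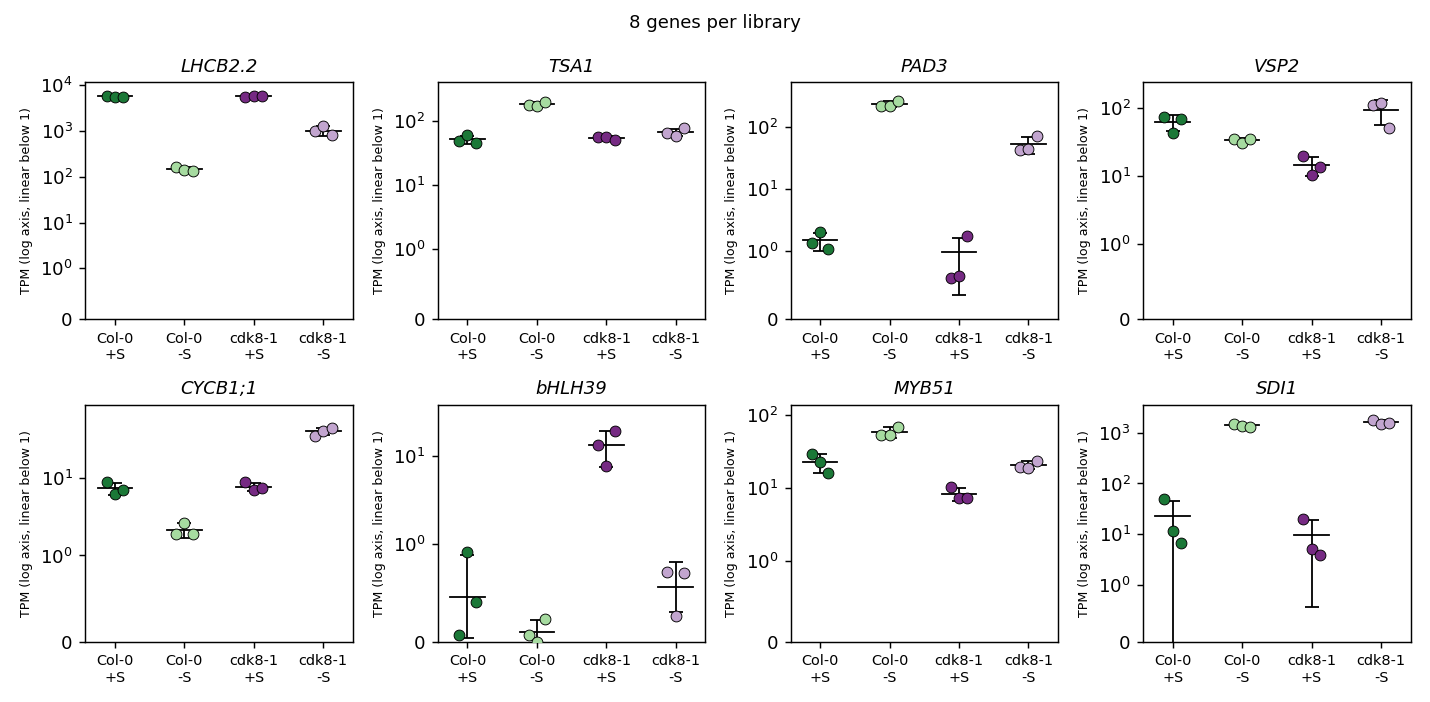
TPM of 8 genes in each of the 12 libraries, on axes that are logarithmic above 1 and linear below it. Points are libraries, and bars are the group mean and SD. Without sulfate LHCB2.2, VSP2 and CYCB1;1 are higher and TSA1, PAD3 and MYB51 lower in cdk8-1 than in Col-0, while bHLH39 is higher in cdk8-1 with sulfate.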

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

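The tests of scaling, of mixed material, of milder deprivation and of dividing cells were chosen only after the results they bear on had been seen. The smaller sulfur response of cdk8-1, CYCB1;1, VSP2 and ABCG40 stand out because the responses of the genotypes to sulfur supply differed in a test of that difference. The rise of bHLH38, bHLH39 and BHLH100 was not flagged in that way and was picked for its size in 1 comparison. Groups of 3 libraries are too small for a search for outlying samples, and none was made.

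The first pattern is the smaller sulfur response of cdk8-1, where 5171 genes passed the interaction test, the photosynthesis list had a median of 1.60, and the tryptophan and camalexin lists had medians of -0.91 and -1.88. Scaling of the TPM columns does not account for the interaction calls, since at least 4813 genes passed under each other scaling. That count does not measure the size of a response. The slope of the response in cdk8-1 on that in Col-0 was 0.741 after median-of-ratios scaling and 0.757 after quantile scaling. A factor per column can hardly move a slope, so the median-of-ratios value is a weak check. Among 100 of the 200 relabellings of genotype within supply, only the real one (1 of 100) reached the real count. That result does not weigh chance for the interaction alone. In 93 draws the genotypes were mixed without sulfate, which adds their difference to the spread, and the highest gave 38 genes. In 6 draws they were kept whole there, and the highest gave 4577. The remaining relabellings were not drawn, so chance stays open. Sulfur-supplied material mixed into the deprived cdk8-1 libraries would leave every abundant gene at least its share. The median photosynthesis gene kept 18.5% (5.54% in Col-0), but 22 of 3329 genes at 50 TPM or more kept less than that share divided by 3. Among them TGG2 kept 0.182 ± 0.0955% and CA1 1.93 ± 0.499%. The bound, set after the results were seen, asked for 20 genes, so the count passed it only narrowly. Milder deprivation would shrink the sulfur limitation markers too, unless they had reached a ceiling, which was not tested. Over 18 of them the median ratio of the cdk8-1 to the Col-0 rise was 1.02 (lowest 0.701, highest 1.27), against a slope of 0.74 over all genes. The markers also started lower in cdk8-1, with a list median of -0.20 against Col-0 with sulfate, which can enlarge the ratio. Milder deprivation is therefore not excluded. An effect of the cdk8-1 genotype on the sulfur response may be a candidate explanation, found and tested on the same data. Chance, milder deprivation and differences between the lines other than CDK8 stay open, as does the growth of the plants, which was not measured here.

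The second pattern is the rise of bHLH38, bHLH39 and BHLH100 in cdk8-1 with sulfate. No single library made it, since the lowest of the 3 log2 changes was 2.80 when 1 cdk8-1 library with sulfate was left out. A wider shoot response to low iron is consistent with the other iron deficiency genes, whose median log2 change was 0.97. Iron itself was not measured, and chance cannot be weighed by 10 splits of 6 libraries. For the count of all 2618 genes of this comparison the highest other split gave 18.

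The third pattern is CYCB1;1, with an interaction of 3.62. The other cell division genes reached at most 1.50. CYCB1;1 was picked for its large value, and this test was chosen after that value had been seen. The gap therefore cannot decide whether more dividing cells account for it. A DNA damage response, in which CYCB1;1 is known to be induced, is consistent with a median interaction of 0.97 over the DNA damage list. DNA damage was not measured, and the 2 explanations may hold side by side.

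VSP2 had an interaction of 3.39, with 62.5 ± 16.9 TPM with and 33.6 ± 3.01 TPM without sulfate in Col-0, and 14.6 ± 4.64 and 93.8 ± 37.8 TPM in cdk8-1. ABCG40 had an interaction of -5.79, with 332 ± 33.4 TPM without sulfate in Col-0 and 4.78 ± 1.62 TPM in cdk8-1.

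The other 3 comparisons of 2 groups have 10 splits of 6 libraries each, too few for a share under 0.05, and in each 1 of 10, the real one, reached the real count. The real counts and highest other counts were 16248 and 0 for sulfur in Col-0, 15607 and 0 for sulfur in cdk8-1, and 7900 and 1 for genotype without sulfate.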

How the results depend on the processing

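Limma voom on recovered reads and an estimated list correlation after median-of-ratios scaling were the alternatives chosen only after the data had been seen. Under all scalings, filters, pseudocounts, moderations and array weights, the 5 gene counts stayed within 1.5 times, and only 3 settings moved them further. A 2-fold minimum gave 9103, 7407, 285, 1814 and 1768 genes (sulfur in Col-0, sulfur in cdk8-1, genotype with sulfate, genotype without, interaction), as fewer genes reach it. With only the 6 libraries compared, genotype with sulfate gave 1183 genes, the spread then resting on fewer samples. Without 1 library the counts were 15770 to 15964, 15004 to 15215, 1744 to 2408, 6558 to 6955 and 4265 to 5266, where 1744 was genotype with sulfate without cdk8-1 with sulfate replicate 3 (2618 with all). The labels do not say that replicate numbers pair samples. Correlations of residuals were -0.004 to 0.305 between libraries of one number (median 0.073) and -0.240 to 0.125 between numbers (median -0.054). In 22 of 36 combinations a library correlated best with its own number, a hint from the data and not from the design. A block by number gave 16363, 15771, 3220, 8377 and 5718 genes and changed 3 list calls. For genotype with sulfate, sulfate assimilation did not pass (adjusted p = 0.0506) and senescence did (0.0328), and sulfate assimilation passed for genotype without (0.0392). The correlation of the 2 sulfur responses was 0.924 with a pseudocount of 0.1, 0.924 with no filter and 0.949 with a minimum of 5 TPM, and the slope 0.729 with a pseudocount of 0.1 and 0.757 with quantile scaling. The cause was not tested. Other pseudocounts added 2 (0.1) and 1 (0.5) list calls and ended 0. No filter added 4 and ended 1, a minimum of 5 TPM added 1 and ended 2, and median-of-ratios and quantile scaling each added 3 and ended 1. Of 39 list calls 38 were lost with an estimated correlation, which left 0, 0, 0, 1 and 0 on the deposited scale and after median-of-ratios scaling, while fry called 19 and 16 lists under sulfur and 6 for genotype with sulfate. Of 308 named gene values, 300 kept their side after median-of-ratios scaling, 298 after quantile scaling and 215 of 242 with only the 6 libraries. In 2244 runs without 1 library 2177 kept it. The interaction of CDK8, never past the test, was -0.13, and -0.283 to 0.0154 without 1 library (highest without cdk8-1 with sulfate replicate 3), and that of CYP94B3 went from -1.16 to 0.53 with voom. Depth limits genes near 1 TPM, where 1 read in 1 kilobase is up to 0.0962 TPM. Correlation, slope and lists were not run under voom.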

Other observations

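The lists of iron deficiency genes, ferritins and DNA damage genes were chosen only after the data had been seen, with members fixed before their own values were looked at, and the test of dividing cells was chosen after its result. In cdk8-1 with sulfate, all 10 tested genes of the iron deficiency list were higher than in Col-0 (10 adjusted over the list alone), with a median log2 fold change of 0.97 (camera unadjusted p of 9.88e-11, and of 0.00966 with an estimated correlation). The list leaves out bHLH38, bHLH39 and BHLH100. IMA1, for a small peptide that acts in iron signaling, went from 1.60 ± 0.700 to 10.8 ± 4.01 TPM (2.15), bHLH101 from 3.27 ± 1.09 to 14.1 ± 4.15 TPM (1.81), and BTS, for a ubiquitin ligase, from 54.7 ± 6.98 to 102 ± 10.98 TPM (0.89). Ferritin genes, for iron storage, were lower in 2 of 4 (3 adjusted over the list alone or after median-of-ratios scaling). FER1 went from 210.2 ± 44.9 to 55.8 ± 4.45 TPM (-1.87) and FER4 changed by -1.004. Without sulfate 4 of 10 iron deficiency genes were higher in cdk8-1 and 3 ferritins lower, and in the interaction 1 of the 10 was positive and 6 negative, with 1 ferritin negative. Under sulfur deprivation 1 iron gene was higher and 7 lower in Col-0, and 8 were lower in cdk8-1, with 2 ferritins higher in each genotype. After median-of-ratios scaling 1 iron gene was higher and 9 lower in Col-0, and 10 were lower in cdk8-1. Ferritins were then 2 higher and 1 lower in Col-0, and 1 and 1 in cdk8-1.

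In cdk8-1 without sulfate, all 14 tested DNA damage genes were higher than in Col-0 (14 adjusted over the list alone), with a median of 1.42 (camera unadjusted p of 1.21e-09, and of 0.0023 with an estimated correlation). SMR7, for an inhibitor of the cell cycle, went from 0.686 ± 0.513 to 14.1 ± 1.93 TPM (3.20), PARP2 from 9.74 ± 0.402 to 41.7 ± 2.85 TPM (1.99) and BRCA1 from 1.21 ± 0.0403 to 6.63 ± 1.04 TPM (1.78). The interaction was positive in 13 of the 14 (14 adjusted over the list alone), and GMI1 missed it at 0.40. After median-of-ratios scaling it was positive in 12. With sulfate 3 genes of this list were higher in cdk8-1 (2 after scaling). Under sulfur deprivation 5 were higher and 5 lower in Col-0 (4 and 6 after scaling), and 10 higher and 2 lower in cdk8-1 (9 and 3).

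By at least 2-fold in the same direction at both supplies, 95 genes differed between the genotypes. Of these 15 lie on chromosome 5, where CDK8 is, and none other than CDK8 among the 161 tested genes within 100 loci of it.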
